A study of Homo sapiens with 9 samples.

How the data were processed

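RNA sequencing was analysed from 9 libraries of C28/I2 cells, an immortalised human chondrocyte line. The labels put 3 libraries in each of 3 groups, named Control, Scrambled and CA2 shRNA. The labels describe neither the construct of the Scrambled group nor whether the Control cells were transduced. The labels' protocols name RNeasy Mini for total RNA and QIAGEN FastSelect, a kit that removes ribosomal RNA. Nothing in the labels says that the replicates came from separate cultures, so the p-values measure the spread between these samples, which may be technical.

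The authors deposited 1 table per library with the same 60671 Ensembl genes. Each table gives the read count of a gene as a whole number, its CPM and its RPKM, per the file headers. The deposited CPM equalled the count divided by the sum of counts, and the deposited RPKM equalled CPM divided by the summed exon length in kilobases, when both were recomputed. Per the submitters' processing notes, reads were handled with bcl2fastq, STAR 2.5.1a and featureCounts 1.4.6-p5 of the Subread package on GRCh38. The annotation release, the strand setting, the read layout and the treatment of reads that map to several places are not given in the sources used here. Reads of overlapping genes and of near-identical copies could therefore be split or lost, which concerns SOD2 and ACAT2 (neighbours on opposite strands), SLC2A3 and SLC2A14, HSPA1A and HSPA1B, the histone genes, KRT8 and its pseudogenes, and ZNNT1. Symbols for 60401 gene IDs came from a reference table and 246 more from GENCODE 29. Every line of the tables named a gene.

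The deposited counts were the input to every test. Totals ranged from 16994368 to 34261244 counts per library. No pair of libraries agreed within sampling noise: the chi-square per gene ranged from 3.7 to 30.27 over all pairs and was at least 4.64 within a group, so no library was counted as a duplicate. Genes were kept by edgeR's filterByExpr with the 3 groups, which left 19812. Counts were scaled with TMM factors, which lay between 0.977 and 1.012. The main test was edgeR's quasi-likelihood F test with robust fitting on all 9 libraries in 1 model with a term per group, which leaves 6 residual degrees of freedom. The p-values were Benjamini-Hochberg adjusted, with a threshold of 0.05 and no limit on the fold change. The biological coefficient of variation was 7.9%. Printed levels are TMM-scaled CPM as mean ± SD over the 3 libraries of a group. An exact permutation test of 3 against 3 libraries cannot go below 0.10, so none is given for single genes.

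The groups were compared as CA2 shRNA against Scrambled, CA2 shRNA against Control and Scrambled against Control, and genes passing the threshold in both CA2 shRNA comparisons with the same sign were counted. The overlap was set beside that of independent lists and beside 10 simulations with no effect that kept the shared libraries. The comparisons, the tests, 36 gene lists and the rule for naming genes were fixed before the data were examined. Lists with at least 3 tested members were tested with limma's camera on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, Benjamini-Hochberg adjusted over the lists. Beside it stand the members past the threshold over all genes and adjusted over the list alone, camera with an estimated correlation, and fry. For every list that passed in a CA2 shRNA comparison, the value with an estimated correlation was the highest adjusted p over its alternatives, and the lowest is given after it. The lists cover carbonic anhydrases, acid-base and lactate transporters, vacuolar ATPase subunits, glycolysis, the tricarboxylic acid cycle, nuclear and mitochondrial genes of oxidative phosphorylation, hypoxia-inducible factor targets, antioxidant genes, cartilage matrix, matrix-degrading enzymes, fibroblast-like matrix, hypertrophy, nuclear factor kappa B, interferon, endoplasmic reticulum stress, ATF4 targets, p53 targets, apoptosis, S phase, G2 and mitosis, histones, cholesterol, fatty acid synthesis, fatty acid oxidation, lysosome, TGF-beta targets, YAP targets, heat shock proteins, ribosomal proteins, small RNA machinery, and markers of immune, endothelial, epithelial, neural, and adipocyte or muscle cells.

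Named genes were CA2, then the 10 largest rises and 10 largest falls against Scrambled and the 5 and 5 in each of the other comparisons. These were taken among protein-coding genes past the threshold with a mean CPM of at least 2 and with all 3 libraries of one group above all 3 of the other, a separation that chance gives in 10% of genes. From each list up to 4 members with the largest changes among those past the threshold were eligible, or 2 with the highest level, with values only, where none passed. For both controls together the rule took the 10 genes with the largest smaller-of-the-pair change.

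Alternatives were DESeq2 size factors in edgeR, upper-quartile factors, library totals, no filter, a filter of at least 1 CPM in 3 libraries, DESeq2's Wald test, limma-voom, the replicate number as a block, a limit of 1 on the absolute log2 fold change, thinning all libraries to the smallest total of 16994368, protein-coding genes only, the 6 libraries of a comparison alone, and leaving out each library in turn. After seeing the data, offsets corrected for GC content (available for 98.4% of tested genes), leaving out Control 3 and Scrambled 2 together, and keeping only genes whose annotated 3' UTR of at least 50 bases holds neither ACACCAA nor CACCAAA were added. Camera compares list members with all other genes in the fit. Against Scrambled the median log2 change was 0.038 among genes with neither heptamer fitted alone and -0.025 in the main fit. Against Control it was 0.035 and -0.005. A list can therefore lose its call there even if none of its members held a heptamer. The heptamer scan used the longest annotated 3' UTR (GENCODE 29) of 12017 genes with a mean CPM of at least 2 and regressed the log2 fold change on the presence of each of 16251 heptamers found in at least 50 genes, with 3' UTR length, GC content and expression as covariates.

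The edgeR and list steps were tested on simulated data drawn for CA2 shRNA against Scrambled over the 19812 genes. Of 100 genes changed 1.5-fold 75 were recovered, of 100 changed 2-fold 96, and 9 unchanged genes were called. Of 10 planted lists 10 passed, and of 36 lists of unchanged genes 0 passed. No correlation between genes was planted in these lists, so they cannot show false calls that arise from the preset correlation. Each planted list mixed unchanged genes with genes raised 1.5-fold or 2-fold. They therefore cannot show how small shifts of most members, as in many real lists, are called. In the real lists the estimated correlation ranged from -0.011 (fibroblast-like matrix) to 0.795 (mitochondrially encoded proteins). With an estimated correlation 0 of the 36 real lists passed against Scrambled. In the heptamer scan 20 of 20 heptamers planted on shuffled fold changes ranked first. The planted log2 difference of -0.25 was about that observed for ACACCAA (-0.247), so the scan was not tried on weaker effects. R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.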

Results

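RNA was sequenced from C28/I2 cells, an immortalised line of human chondrocytes, in 9 libraries. The series title names carbonic anhydrase 2 (CA2) as required for the metabolic homeostasis of articular chondrocytes, and the design compares cells transduced with a short hairpin RNA (shRNA) against CA2 with Scrambled and Control cells, 3 libraries each. Total counts were 23721190, 20715858 and 34261244 in Control, 22352961, 27017588 and 29605026 in Scrambled, and 19960657, 16994368 and 27070048 in CA2 shRNA. Mitochondrial genes took 5.29% ± 1.07, 5.73% ± 1.46 and 5.93% ± 0.603 of the counts (SD, n = 3 each). Among the controls, Control 3 and Scrambled 2 stood apart from the other libraries. They held 4.06% and 4.08% mitochondrial counts and 159 and 233 CPM of the nuclear RNA NEAT1, against 312.5 to 680 CPM in the other 4 control libraries and 266 to 526.8 CPM in the CA2 shRNA libraries. NEAT1 was picked after its values were seen.

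CA2 (ENSG00000104267), the cytosolic enzyme that hydrates carbon dioxide, was lower in every CA2 shRNA library than in any control library. The gene lies on the plus strand of chromosome 8 from 85463968 to 85481493 (GRCh38). Its counts were 55, 41 and 66 in Control, 41, 53 and 61 in Scrambled, and 28, 15 and 30 in CA2 shRNA. The levels were 2.31, 2.00 and 1.94 CPM in Control (mean 2.08 ± 0.20, SD, n = 3), 1.82, 1.96 and 2.06 CPM in Scrambled (1.95 ± 0.122) and 1.4, 0.905 and 1.10 CPM in CA2 shRNA (1.13 ± 0.248). The CA2 shRNA mean was 58.2% of the Scrambled and 54.4% of the Control mean. CA2 fell by 0.77 on the log2 scale against Scrambled (SE 0.231, adjusted p = 0.0276) and by 0.86 against Control (SE 0.23, adjusted p = 0.0159), while Scrambled less Control was -0.09 (adjusted p = 1). At these low counts the call was fragile. Against Scrambled it held in 16 of 23 alternatives (adjusted p 0.0181 to 0.109) and was lost without Scrambled 2 (0.0533), Scrambled 3 (0.103), CA2 shRNA 2 (0.1) or CA2 shRNA 3 (0.109), without the filter (0.0544), after thinning (0.0571) and with DESeq2 (0.0524). Against Control it held in 19 of 23 (adjusted p 0.0101 to 0.0759) and was lost after thinning (0.0652) and without Control 1 (0.0531), CA2 shRNA 2 (0.0665) or CA2 shRNA 3 (0.0759).

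**Figure D1:**
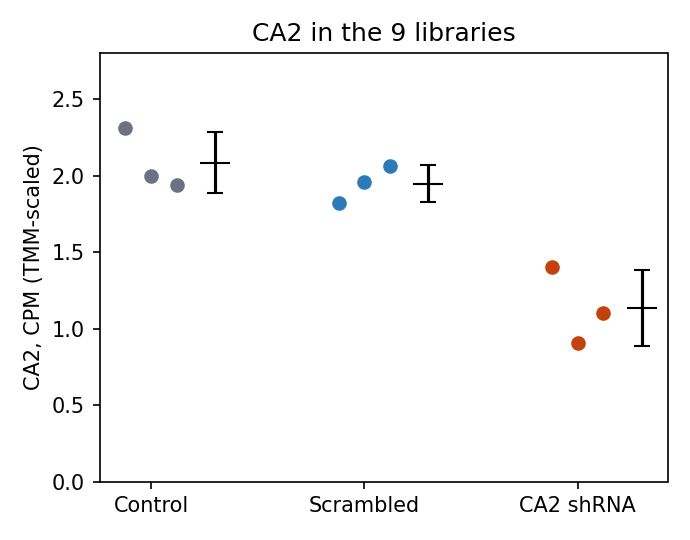
CA2 level in TMM-scaled CPM (vertical axis, from 0) for each library of the Control, Scrambled and CA2 shRNA groups, with the mean and SD of 3 libraries beside the points. The CA2 shRNA libraries lie at 0.905 to 1.4 CPM and the 6 control libraries at 1.82 to 2.31 CPM.

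Against Scrambled, the control group named for a scrambled construct, the glucose transporter SLC2A3 rose from 11.9 ± 0.627 to 35.4 ± 4.11 CPM (SD, n = 3 each). The prostaglandin E synthase gene PTGES rose from 14.9 ± 0.223 to 38.5 ± 3.91 CPM. These were changes of 1.57 (SE 0.103, adjusted p = 1.08e-08) and 1.37 (SE 0.094, adjusted p = 1.81e-08) on the log2 scale. Reads of SLC2A3 are uncertain because its paralog SLC2A14 is nearly identical. The secreted Wnt antagonist FRZB rose from 2.63 to 6.65 CPM, and the deubiquitinase gene YOD1 from 19.6 to 44.7 CPM. On the log2 scale, the receptor kinase gene MST1R rose by 1.18, C1QTNF2 by 1.17, CD83 by 1.16, the axon guidance gene SEMA3A by 1.12, and MPZL3 and the acyltransferase GPAT3 by 1.10 each. PPDPF fell from 489 ± 25.1 to 134 ± 2.74 CPM, a log2 change of -1.87 (SE 0.061, adjusted p = 2.48e-12), and the acyl-CoA thioesterase ACOT7 from 126 ± 5.56 to 44.4 ± 1.24 CPM (-1.51, SE 0.057, adjusted p = 1.68e-11). The focal adhesion gene LPP fell from 199.6 ± 45.9 to 64.9 ± 5.57 CPM (adjusted p = 0.000342) and MARCKS, a substrate of protein kinase C, from 218 ± 39.1 to 71.9 ± 16.3 CPM (adjusted p = 0.0028). The remaining leading falls were AMTN (-2.01), the transcription factor ONECUT2 (-1.68), FBXL7 (-1.61), ELFN1 (-1.55), the tight junction gene CLDN3 (-1.52) and LPGAT1 (-1.48). In all, 1589 genes rose and 1759 fell, 3348 of 19812 tested, with a median absolute log2 change of 0.38, and 5746 passed at an unadjusted p under 0.05. Changes of at least 2-fold were 36 rises and 173 falls. The balance of directions depended on the setting: rises outnumbered falls in 10 of the 23 alternatives with no limit on the fold change, such as DESeq2 (1811 and 1512). Rises numbered 864 without Scrambled 3, 906 without CA2 shRNA 2 and 2407 without Control 3 and Scrambled 2, and falls 1129 without CA2 shRNA 1 and 1164 without CA2 shRNA 3. Without Scrambled 3 the count was 2059, and without Control 3 and Scrambled 2 it was 4289. Of the 10 leading falls 8 held ACACCAA or CACCAAA in their 3' UTR, and of the 10 leading rises 2 did, a feature chosen after the values were seen.

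Genes of acid-base balance and carbon metabolism moved in both directions. The monocarboxylate transporter SLC16A1, which carries lactate, rose from 76.3 ± 5.23 to 114.7 ± 1.62 CPM (log2 change 0.59) and its relative SLC16A3 by 0.33, while the sodium-proton exchanger SLC9A7 fell (-0.44). Of 22 tested acid-base and lactate transporters 3 rose, 1 fell and 18 did not pass (3 and 1 adjusted over the list alone), and the list did not pass (adjusted p = 0.285), with a median of 0.066 and a test direction up against a mean of -0.001. Of 8 carbonic anhydrases CA12 rose by 0.85, CA2 fell and 6 did not pass, with 1 and 1 adjusted over the list alone (list adjusted p = 0.828). The rise of CA12 did not pass against Control, where 0 of the 8 rose and 1 fell, also adjusted over the list alone (list adjusted p = 0.401). Among 17 vacuolar ATPase subunits, which acidify organelles, 3 rose, 2 fell and 12 did not pass (3 and 2 adjusted over the list alone), with ATP6V0E1 at -0.88 and ATP6V1B2 at 0.39 (list adjusted p = 0.0955). In glycolysis 8 of 21 members rose, among them PGAM1 (0.39) and TPI1 (0.37), 2 fell, including the regulatory enzyme gene PFKFB3 (-0.69), and 11 did not pass (8 and 2 adjusted over the list alone). The glycolysis list rose (adjusted p = 0.0173), with adjusted p = 0.62 with an estimated correlation, lowest alternative 0.000669 and 0.126 without CA2 shRNA 1. Of 22 genes of the tricarboxylic acid cycle 6 rose, such as SUCLG2 (0.31) and OGDH (0.29), 4 fell and 12 did not pass (6 and 4 adjusted over the list alone, list adjusted p = 0.0848). Nuclear genes of oxidative phosphorylation rose as a list by a small amount (median 0.118, adjusted p = 5.29e-05, adjusted p = 0.62 with an estimated correlation, lowest alternative 2.58e-07). Of 71 members 7 rose, 0 fell and 64 did not pass (2 and 0 adjusted over the list alone). A 3' UTR heptamer was held by 3 of the 70 searched members. Scanned genes with no 6 adjoining bases of ACACCAAA in the 3' UTR had a median of 0.06 themselves, which is part of the list's 0.118. Of 13 mitochondrially encoded proteins 0 passed, also adjusted over the list alone (list adjusted p = 0.136), with MT-CO1 at 10530 ± 2830 CPM in Scrambled and 9903 ± 1240 CPM in CA2 shRNA. Of 22 targets of hypoxia-inducible factors 5 rose, including the oxidase gene ERO1A from 46.7 to 71.5 CPM and PGK1 by 0.35, 0 fell and 17 did not pass (7 and 0 adjusted over the list alone). That list rose (adjusted p = 0.000814), with adjusted p = 0.599 with an estimated correlation, lowest alternative 1.87e-05 and 0.0698 without CA2 shRNA 1. Of 24 antioxidant genes 5 rose, such as NQO1 (0.30) and GPX1 (0.27), 2 fell, with GCLM of glutathione synthesis at -0.63, and 17 did not pass (6 and 2 adjusted over the list alone). The antioxidant list rose (adjusted p = 0.0208), with adjusted p = 0.62 with an estimated correlation, lowest alternative 0.00457, 0.107 without Scrambled 3 and 0.0847 without CA2 shRNA 2. It was also lost among genes with neither 3' UTR heptamer (0.145). SLC9A7, ATP6V0E1, PFKFB3 and GCLM held at least 1 of them.

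Several matrix genes and 13 of 22 targets of transforming growth factor beta (TGF-beta) fell, while neither the fibroblast-like nor the cartilage matrix list passed with camera. FBN1, which encodes the microfibril protein fibrillin, fell from 259 ± 18.3 to 104 ± 6.98 CPM (log2 change -1.31, adjusted p = 1.28e-09), and the matricellular gene CCN2 from 136 ± 5.64 to 62.3 ± 1.15 CPM (-1.13, adjusted p = 4.83e-10). The collagen genes COL5A1 (855 to 515 CPM), COL3A1 (-0.88) and COL12A1 (-0.83) also fell, and these 3 held at least 1 of the 3' UTR heptamers, while FBN1 and CCN2 held neither. In the fibroblast-like matrix list 1 of 15 members rose, 5 fell and 9 did not pass (4 and 6 adjusted over the list alone), with a heptamer in 3 of the 5 falling members, and the list did not pass (adjusted p = 0.108). Of 22 TGF-beta and SMAD targets 13 fell, including the smooth muscle genes TAGLN (-0.77) and TPM1 (-0.58), 2 rose and 7 did not pass (2 rises and 16 falls adjusted over the list alone). The TGF-beta list fell (median -0.308, adjusted p = 4.01e-05), with adjusted p = 0.121 with an estimated correlation, lowest alternative 1.01e-05, and 4 of its 13 falling members held at least 1 of the 3' UTR heptamers. Of 20 YAP and TEAD targets 4 rose, 7 fell, such as the receptor kinase gene AXL (850 to 467 CPM) and IGFBP3 (-0.69), and 9 did not pass (5 and 7 adjusted over the list alone, list adjusted p = 0.285). CCN2 is a member of both lists. AXL and TPM1 held both heptamers. In the cartilage list 1 of 17 genes rose and 1 fell, also adjusted over the list alone, and 15 did not pass (list adjusted p = 0.257). The cartilage matrix gene COMP went from 2.48 to 1.34 CPM (-0.86, adjusted p = 0.0161), a call lost without CA2 shRNA 2 (0.0725, alternatives 0.00957 to 0.0725). The chondrocyte regulator SOX9 went from 90.9 to 104.6 CPM (0.20, adjusted p = 0.0364). The SOX9 call was lost without Control 2 (0.0774), Scrambled 1 (0.0541), Scrambled 3 (0.0898), CA2 shRNA 1 (0.0568) or CA2 shRNA 2 (0.121), with upper-quartile factors (0.0566) and after thinning (0.0517), with alternatives from 0.00692 to 0.121. Of 19 matrix-degrading enzymes and inhibitors the collagenase gene MMP1 (0.54), PLAT (0.47) and 4 others rose, 3 fell and 10 did not pass (7 and 3 adjusted over the list alone). The rise of that list was marginal (adjusted p = 0.0497, adjusted p = 0.549 with an estimated correlation, lowest alternative 0.0235) and was lost with DESeq2 size factors (0.0552), without CA2 shRNA 2 (0.0847) and among genes with neither 3' UTR heptamer (0.432). Of 14 genes of hypertrophy and ossification 1 rose, 2 fell, with ENPP1 of pyrophosphate metabolism, which held both heptamers, at -0.86, and 11 did not pass (1 and 3 adjusted over the list alone, list adjusted p = 0.108).

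Some genes of inflammation and stress rose, while most members of these lists other than that of endoplasmic reticulum stress did not pass. TNFAIP3, an inhibitor and target of nuclear factor kappa B, doubled from 19.2 ± 0.267 to 38.7 ± 1.85 CPM (SD, n = 3, log2 change 1.01, adjusted p = 2.71e-08), BIRC3 rose by 0.84, the cyclooxygenase gene PTGS2 by 0.67 and NFKB2 by 0.43. Of 21 genes in the nuclear factor kappa B and cytokine list 8 rose, 0 fell and 13 did not pass (11 and 0 adjusted over the list alone). The list rose (adjusted p = 4.64e-05, adjusted p = 0.456 with an estimated correlation, lowest alternative 2.00e-05). Of 29 interferon-stimulated genes 7 rose, 0 fell and 22 did not pass, with the same counts of 7 and 0 adjusted over the list alone. OASL rose from 1.15 to 3.45 CPM, IFIT2 by 0.73, SAMD9 by 0.67 and USP18 by 0.67. The interferon list rose (adjusted p = 5.29e-05, adjusted p = 0.214 with an estimated correlation, lowest alternative 3.17e-05). Of 19 endoplasmic reticulum stress genes 11 rose, including the chaperone genes DNAJB9 (0.61), SDF2L1 (0.44) and CALR (1743 to 2215 CPM), 1 fell and 7 did not pass (12 and 1 adjusted over the list alone). The list rose (adjusted p = 5.29e-05, adjusted p = 0.488 with an estimated correlation, lowest alternative 3.17e-05). Of 25 ATF4 targets SESN2 rose by 0.53, the amino acid transporter gene SLC7A5 fell (-0.26) and 23 did not pass (1 and 1 adjusted over the list alone, list adjusted p = 0.396). Among 22 p53 targets 7 rose, such as the death receptor gene TNFRSF10B (0.49) and TP53INP1 (0.48), 2 fell and 13 did not pass (8 and 2 adjusted over the list alone). The p53 list rose (adjusted p = 0.0208, adjusted p = 0.488 with an estimated correlation, lowest alternative 0.00923), a call lost among genes with neither 3' UTR heptamer (0.0709). A heptamer was held by 4 of its 21 searched members, with 1 of the 2 falling and 0 of the 7 rising members among them. Of 30 apoptosis regulators, which include promoters and inhibitors of cell death, 9 rose, among them the inhibitor gene BIRC3, 2 fell, including the pro-apoptotic BMF (-0.61), which held both heptamers, and 19 did not pass (9 and 3 adjusted over the list alone). The list rose (adjusted p = 0.00486, adjusted p = 0.488 with an estimated correlation, lowest alternative 0.00229). Of 18 heat shock proteins 5 rose, such as HSPA4L (0.45) and BAG3 (0.30), 1 fell and 12 did not pass (6 and 1 adjusted over the list alone). The heat shock list rose (adjusted p = 0.0346), with adjusted p = 0.629 with an estimated correlation, lowest alternative 0.00194, and was lost without Scrambled 1 (0.0693), Scrambled 3 (0.182) or CA2 shRNA 2 (0.0847), and among genes with neither 3' UTR heptamer (0.193). A heptamer was held by 0 of its 18 members, so that last loss does not come from members taken out.

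Proliferation and lipid genes gave mixed counts. The replication clamp gene PCNA fell from 337 ± 1.35 to 186 ± 4.01 CPM (log2 change -0.86, adjusted p = 5.49e-09), and held 1 of the 3' UTR heptamers. Of 27 S phase genes 11 rose, among them DTL (0.36), FEN1 (0.35) and GINS2 (0.32), 2 fell including PCNA, and 14 did not pass (12 and 2 adjusted over the list alone), with a heptamer in 2 of the 2 falling and 0 of the 11 rising members. The S phase list rose (adjusted p = 0.00225, adjusted p = 0.549 with an estimated correlation, lowest alternative 0.000669). The proliferation marker MKI67 fell from 1821 ± 163 to 1238 ± 80.5 CPM. CDC25C (-0.74), CCNB2 (-0.55) and the mitotic kinase gene PLK1 (-0.28) also fell. Of 29 genes of G2 and mitosis 2 rose, 6 fell and 21 did not pass (3 and 7 adjusted over the list alone, list adjusted p = 0.297). Of 37 replication-dependent histones H2BC7 fell (-0.27) and 36 did not pass, with 0 and 1 adjusted over the list alone. The histone list fell (adjusted p = 0.045, adjusted p = 0.78 with an estimated correlation, lowest alternative 0.000767), a call lost with DESeq2 size factors (0.0834) and without Control 3 (0.0626), Scrambled 1 (0.511), Scrambled 2 (0.0997), CA2 shRNA 1 (0.314) or CA2 shRNA 3 (0.382). It was lost too without both Control 3 and Scrambled 2 (0.133) and with offsets corrected for GC content (0.0884). Of 25 cholesterol genes 5 rose, including HMGCS1 (0.38), 1 fell and 19 did not pass (5 and 1 adjusted over the list alone). The cholesterol list rose (adjusted p = 0.00614, adjusted p = 0.62 with an estimated correlation, lowest alternative 0.000767). Of 19 fatty acid and triglyceride synthesis genes ELOVL6 rose by 0.50, FASN (-0.34), AGPAT2 (-0.36) and FADS1 (-0.29) fell and 15 did not pass (2 and 3 adjusted over the list alone, list adjusted p = 0.771). Of 19 fatty acid oxidation genes 1 rose, 1 fell and 17 did not pass (1 and 1 adjusted over the list alone, list adjusted p = 0.136). Of 26 lysosome and autophagy genes 5 rose, such as the regulator TFEB (0.69) and LAMP2 (0.42), MAP1LC3B fell (-0.52) and 20 did not pass (7 and 3 adjusted over the list alone, list adjusted p = 0.0912). Of 73 cytosolic ribosomal proteins 0 rose, 2 fell, with RPL18 at -0.43, and 71 did not pass (0 and 2 adjusted over the list alone, list adjusted p = 0.0955). Of 16 genes of the small RNA machinery the nuclease gene DICER1 (0.44), TNRC6A (0.35) and 4 others rose, TNRC6B fell (-0.69) and 9 did not pass (6 and 2 adjusted over the list alone). The small RNA list rose (adjusted p = 0.0419), with adjusted p = 0.549 with an estimated correlation, lowest alternative 0.0229, 0.0897 without Scrambled 1 and 0.069 without CA2 shRNA 2. It was also lost among genes with neither 3' UTR heptamer (0.11). CDC25C, CCNB2, FASN, MAP1LC3B and TNRC6B held at least 1 of them.

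The lists of markers of other cell types did not pass with camera. Of 5 immune markers 0 passed, also adjusted over the list alone (list adjusted p = 0.697), with CD14 at 1.96 ± 0.115 and 1.29 ± 0.242 CPM. Of 8 endothelial markers 0 passed, also adjusted over the list alone (list adjusted p = 0.731), with FLT1 at 31.1 and 31.0 CPM, and there the median (-0.065) and mean (-0.029) were below 0 while the test pointed up. Of 9 epithelial markers CLDN3 fell, KRT8 rose by 0.22 (adjusted p = 0.0142) and 7 did not pass, with 1 and 1 adjusted over the list alone (list adjusted p = 0.793). The KRT8 call was lost without Scrambled 3 (0.101) or CA2 shRNA 2 (0.0902), with alternatives from 0.00234 to 0.101. Of 7 neural markers SNAP25, which held both 3' UTR heptamers, fell (-0.80) with 1 other and 5 did not pass (0 and 2 adjusted over the list alone, list adjusted p = 0.0958). Of 6 adipocyte and muscle markers 2 fell and 4 did not pass (0 and 2 adjusted over the list alone, list adjusted p = 0.163). Of the 36 lists 16 passed with the preset correlation, 0 with an estimated one and 13 with fry, of which 8 passed with camera and fry alike. Glycolysis (fry adjusted p = 0.129), nuclear oxidative phosphorylation (0.145), hypoxia-inducible factor targets (0.145), antioxidant genes (0.145), S phase (0.0505), histones (0.314), cholesterol (0.145) and heat shock proteins (0.145) passed with camera and not with fry. Fibroblast-like matrix (0.000488), hypertrophy (0.00711), YAP targets (0.00952), neural markers (0.00196) and adipocyte and muscle markers (0.0271) fell with fry and did not pass with camera, with adjusted p from 0.488 to 0.78 with an estimated correlation.

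**Figure D2:**
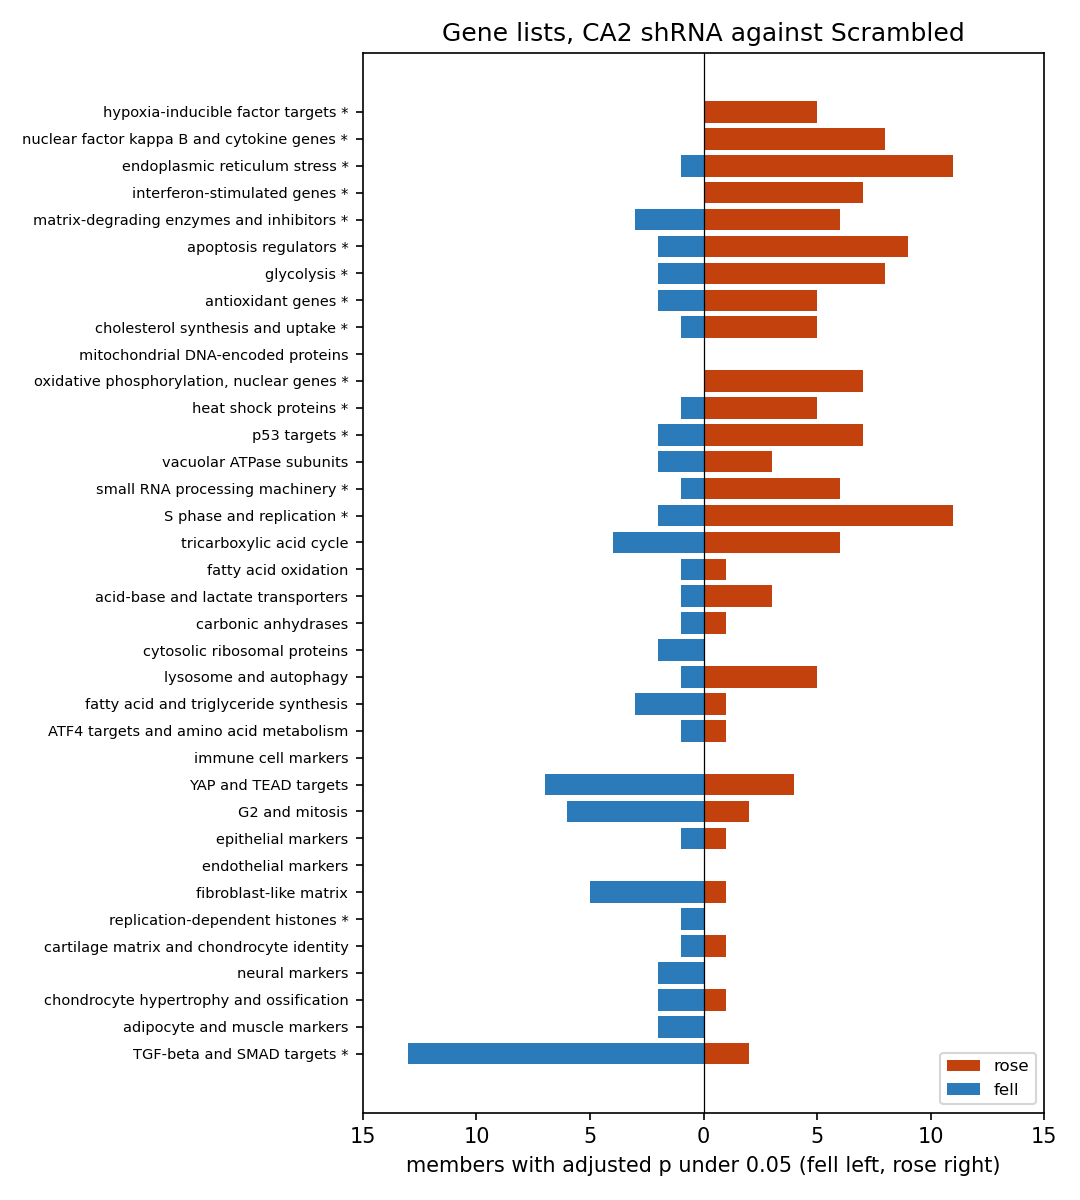
Number of tested members of each of the 36 lists that rose (to the right) or fell (to the left) in CA2 shRNA against Scrambled, ordered by the list's median log2 change, with an asterisk where camera with the preset correlation gave an adjusted p under 0.05. TGF-beta targets had 13 falling and 2 rising members, and the endoplasmic reticulum stress list 11 rising and 1 falling.

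Against Control, the other control group, SLC2A3 rose from 11.9 ± 1.46 to 35.4 ± 4.11 CPM (SD, n = 3 each, log2 change 1.58, SE 0.104, adjusted p = 8.96e-09) and PTGES from 14.2 ± 1.55 to 38.5 ± 3.91 CPM (1.43, adjusted p = 9.61e-09), followed by MST1R (1.38), C1QTNF2 (1.31) and the scramblase gene PLSCR4 (1.21). PPDPF fell from 499 ± 33.1 to 134 ± 2.74 CPM (-1.90, SE 0.061, adjusted p = 1.94e-12), followed by MARCKS (-1.77), AMTN (-1.72), FBXL7 (-1.67) and ACOT7 (-1.64). Counts were 1269 rises and 1637 falls, 2906 genes in all (5237 at an unadjusted p under 0.05), with 31 rises and 156 falls of at least 2-fold, and 3213 genes without Control 3 and Scrambled 2. Rises outnumbered falls in 7 of the 23 alternatives with no limit on the fold change, such as GC-corrected offsets (2051 and 1968). Rises numbered 686 without Control 2, 663 without CA2 shRNA 2 and 2030 without Scrambled 2, and falls 1063 without CA2 shRNA 1. The TGF-beta list fell here too. Of 22 members 2 rose, 13 fell, including CCN2 (-1.23) and TAGLN (-0.92), and 7 did not pass (2 and 16 adjusted over the list alone, list adjusted p = 6.40e-07, adjusted p = 0.0586 with an estimated correlation, lowest alternative 1.39e-07). The nuclear factor kappa B list rose (8 rises and 0 falls of 21 members, 10 and 0 adjusted over the list alone, list adjusted p = 1.31e-05, adjusted p = 0.358 with an estimated correlation, lowest alternative 2.62e-06), with TNFAIP3 at 0.99. The interferon list rose (7 and 0 of 29, 8 and 0 adjusted over the list alone, list adjusted p = 6.59e-05, adjusted p = 0.203 with an estimated correlation, lowest alternative 8.41e-06), with OASL at 1.43. The endoplasmic reticulum stress list rose (10 and 1 of 19, 11 and 1 adjusted over the list alone, list adjusted p = 0.00041, adjusted p = 0.503 with an estimated correlation, lowest alternative 0.000121), with HYOU1 at 0.33. The nuclear oxidative phosphorylation list rose (4 and 0 of 71, 1 and 0 adjusted over the list alone, list adjusted p = 0.000327, adjusted p = 0.713 with an estimated correlation, lowest alternative 3.65e-06). The histone list fell here too (0 and 5 of 37, 0 and 8 adjusted over the list alone, list adjusted p = 0.000808, adjusted p = 0.715 with an estimated correlation, lowest alternative 7.49e-06).

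A further 8 lists passed against Control and lost their call when single libraries were left out. The list of apoptosis regulators rose (8 rises and 2 falls of 30 members, 11 and 2 adjusted over the list alone, list adjusted p = 0.00489, adjusted p = 0.504 with an estimated correlation, lowest alternative 0.000928, 0.0541 without Control 1). The list of hypoxia-inducible factor targets rose (5 and 0 of 22, also adjusted over the list alone, list adjusted p = 0.0057, adjusted p = 0.713 with an estimated correlation, lowest alternative 0.000104, 0.3 without CA2 shRNA 1), with PGK1 at 0.49. That call was lost among genes with neither 3' UTR heptamer (0.057). The glycolysis list rose (6 and 2 of 21, 7 and 2 adjusted over the list alone, list adjusted p = 0.0243, adjusted p = 0.713 with an estimated correlation, lowest alternative 0.00119), and was lost without Control 1 (0.0802) or CA2 shRNA 1 (0.172). The p53 list rose (6 and 1 of 22, 9 and 4 adjusted over the list alone, list adjusted p = 0.0243, adjusted p = 0.445 with an estimated correlation, lowest alternative 0.00966), with the cell cycle inhibitor CDKN1A at 0.51, and was lost without Control 1 (0.0924) or CA2 shRNA 3 (0.0549). The S phase list rose (6 and 2 of 27, 8 and 2 adjusted over the list alone, list adjusted p = 0.0243, adjusted p = 0.713 with an estimated correlation, lowest alternative 0.00659), with losses without Control 1 (0.216) or CA2 shRNA 2 (0.0655). Ribosomal protein genes rose as a list (2 and 2 of 73, 0 and 2 adjusted over the list alone, list adjusted p = 0.00574, adjusted p = 0.721 with an estimated correlation, lowest alternative 2.02e-05), with losses without Control 1 (0.273) or CA2 shRNA 2 (0.436) and among genes with neither 3' UTR heptamer (0.162). The fibroblast-like matrix list fell (0 and 5 of 15, 1 and 5 adjusted over the list alone, list adjusted p = 0.0396, adjusted p = 0.358 with an estimated correlation, lowest alternative 0.000222), with FBN1 at -1.31, and was lost without Control 3 (0.0733), Scrambled 2 (0.0504), CA2 shRNA 1 (0.0506) or CA2 shRNA 3 (0.0846). It was lost too without both Control 3 and Scrambled 2 (0.11) and among genes with neither 3' UTR heptamer (0.057). The small RNA list rose (5 and 1 of 16, 6 and 2 adjusted over the list alone, list adjusted p = 0.0407, adjusted p = 0.668 with an estimated correlation, lowest alternative 0.0243) and was lost without Control 1 (0.0541), Control 2 (0.0774), Scrambled 1 (0.0574), CA2 shRNA 2 (0.0655) or CA2 shRNA 3 (0.0521), and among genes with neither 3' UTR heptamer (0.057). With fry 12 lists passed, 8 of them also with camera. Glycolysis (fry adjusted p = 0.133), nuclear oxidative phosphorylation (0.226), hypoxia-inducible factor targets (0.242), S phase (0.226), histones (0.226) and ribosomal proteins (0.442) did not pass with fry, and hypertrophy (0.0274), YAP targets (0.00625), neural markers (0.0151) and adipocyte and muscle markers (0.0151) fell with fry alone. Antioxidant genes (list adjusted p = 0.0883), matrix-degrading enzymes (0.0883), cholesterol genes (0.111) and heat shock proteins (0.523) did not pass here, and the difference from the comparison with Scrambled was not tested. The median and the test differed in sign for immune markers (-0.176 and up), and the mean and the test for endothelial markers (-0.091 and up), heat shock proteins (-0.03 and up) and acid-base transporters (-0.021 and up).

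Against both controls, PPDPF, AMTN, LPP, FBXL7, ONECUT2, MARCKS, ACOT7, the long noncoding RNA ZNNT1 and CLDN3 fell and SLC2A3 rose, which were the 10 genes with the largest smaller-of-the-pair changes. PPDPF changed by -1.87 and -1.90, LPP by -1.62 and -1.62 and ZNNT1 by -1.64 and -1.50 against Scrambled and Control. Of these 10 genes 6 held at least 1 of the 3' UTR heptamers and 1 was not searched. In total 1087 genes rose and 1383 fell in both comparisons, 2470 genes, and 0 passed in opposite directions. Independent lists of these sizes would share 101.8 rises and 145.3 falls, and simulations with no effect that kept the shared libraries gave a mean overlap of 0.1 and at most 1 gene. Those simulations called at most 3 genes in 1 comparison. They therefore cannot give the overlap to be had from lists of the real size that share libraries. The CA2 shRNA libraries enter both comparisons and are too few to be split between them, so part of the overlap may come from them. Without Control 3 and Scrambled 2 the count was 2644. Rises outnumbered falls in 7 of the 22 alternatives with no limit on the fold change, such as GC-corrected offsets (1777 and 1671). Rises numbered 636 without Control 2 and 581 without CA2 shRNA 2, and falls 898 without CA2 shRNA 1.

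**Figure D3:**
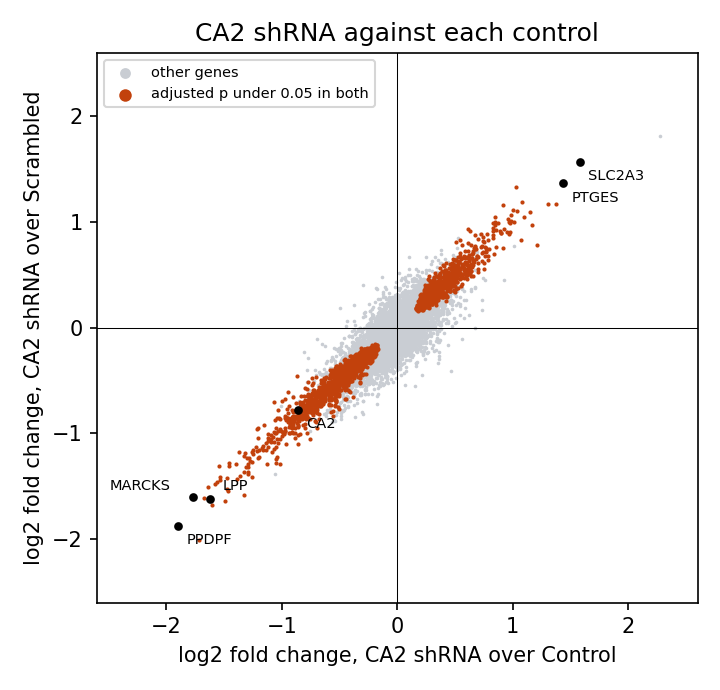
Log2 fold change of CA2 shRNA over Control (horizontal) and over Scrambled (vertical) for genes with a mean of at least 2 CPM, with genes past the threshold in both comparisons in orange. PPDPF lies at -1.90 and -1.87 and SLC2A3 at 1.58 and 1.57, and 0 genes past both thresholds have opposite signs.

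Scrambled against Control compares the 2 control groups, and the labels describe neither the Scrambled construct nor whether Control cells were transduced. SLC2A3 (11.9 CPM in both groups), PPDPF (489 CPM in Scrambled and 499 in Control) and CCN2 (136 and 146 CPM) did not pass. edgeR called 0 of 19812 genes, with 550 at an unadjusted p under 0.05, DESeq2 called 1 and limma-voom 0. The 550 are a smaller share than the 0.05 that chance alone would give. That number was 343 without Control 3, 1435 without Control 1 and 2039 without Scrambled 2. It depended on single libraries, so 0 calls do not show that the control groups are alike. The DESeq2 call was the taste receptor gene TAS1R1 (log2 change 1.64, adjusted p = 0.00507), named after its values were seen, which edgeR called without Scrambled 2 (1.75, adjusted p = 0.0413). Of the lists heat shock proteins were lower by a small amount (median -0.07), with 0 of 18 members passing, also adjusted over the list alone, HSPA8 at 1491 ± 60.8 CPM in Scrambled and 1560 ± 27.3 CPM in Control (SD, n = 3 each) and HSP90AA1 at 1371 ± 128 and 1441 ± 19.9 CPM. The camera test passed (adjusted p = 0.00124) and was lost without Scrambled 3 (0.339), with adjusted p = 0.988 with an estimated correlation and alternatives from 1.75e-05 to 0.997. The median, the mean and the test of the other lists differed in sign for glycolysis, nuclear factor kappa B, matrix-degrading enzymes, G2 and mitosis, fatty acid synthesis, p53 targets, endothelial and neural markers, none of which passed. Leaving out Control 3 and Scrambled 2 also gave 0 genes with edgeR.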

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

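The GC-corrected offsets, leaving out Control 3 and Scrambled 2 together, and keeping genes with neither 3' UTR heptamer were chosen after seeing the data. The counts of changed genes against Scrambled, Control and both controls stayed within 1.5 times under these and the other alternatives, except with a limit of 1 on the absolute log2 change, which left 209, 187 and 121 genes by its construction, and without Scrambled 3, with 2059 against Scrambled. Their rises and falls taken apart moved by more, and which of them were more numerous changed. The 6 libraries of a comparison alone give no count for both controls. Leaving out each library in turn gave 2059 to 4011 genes against Scrambled, 1962 to 3662 against Control, 1750 to 2698 against both, and 0 to 1 for Scrambled against Control (1 without Scrambled 2). That comparison gave 7 genes with no filter and 1 (TAS1R1) with DESeq2, with GC-corrected offsets and among genes with neither heptamer, against 0 in edgeR's test (550 at an unadjusted p under 0.05). The cause was not tested.

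CA2 fell under every alternative run. Against Scrambled it missed the threshold with no filter (-0.77, adjusted p = 0.0544), DESeq2 (-0.76, 0.0524), thinning (-0.75, 0.0571) and without Scrambled 2 (-0.75), Scrambled 3 (-0.73), CA2 shRNA 2 (-0.67) or CA2 shRNA 3 (-0.71), with -0.91 to -0.67 over left-out libraries and adjusted p from 0.0181 to 0.109 over all alternatives. Against Control it missed the threshold with thinning (-0.74, 0.0652) and without Control 1 (-0.78), CA2 shRNA 2 (-0.76) or CA2 shRNA 3 (-0.8), with -1.0 to -0.76 over left-out libraries and adjusted p from 0.0101 to 0.0759. Its counts of 15 to 66 per library limit this test, and the cause was not tested.

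Of the gene lists 0 passed in each comparison with an estimated correlation. Over left-out libraries 12 to 19 passed against Scrambled, 8 (without Control 1) to 16 against Control and 1 to 6 for Scrambled against Control (6 without Control 1, 3 without Scrambled 1 or Scrambled 2, 2 without Control 3 or Scrambled 3). In that comparison 0 passed with fry, 4 with GC-corrected offsets and 2 among genes with neither heptamer. The cause was not tested. Of the other results under the alternatives fixed in advance, 4747 values of named genes kept their direction and side of the threshold, 250 lost the call and 18 changed sign, and 315 list results were kept and 88 lost. Under those added later the numbers were 666, 14 and 3 for genes, with 1 gained, and 81 and 12 for lists. Only lists that passed in the main test were followed, so a gained list call could not appear among these numbers. Named genes were likewise chosen mostly among those that passed.

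The sign changed for 4 genes that did not pass against Scrambled, and the cause was not tested. FLT1 was 0.02 with DESeq2 size factors and DESeq2, 0 with no filter, limma-voom and the 6 libraries alone, 0.01 with at least 1 CPM and GC-corrected offsets, 0.12 without Control 3 and Scrambled 2, and -0.07 to 0.12 over left-out libraries (above 0 without Scrambled 2, CA2 shRNA 1 or CA2 shRNA 2). CSF1R was -0.02 with upper-quartile factors, 0 with library totals, -0.03 with limma-voom and -0.2 (without CA2 shRNA 1) to 0.14 over left-out libraries, with -0.01 without Control 2. MT-ND4 was -0.14 without Control 3 and Scrambled 2 and -0.14 (without Scrambled 2) to 0.22 over left-out libraries, with 0 without CA2 shRNA 1. MT-CO1 was -0.27 to 0.07 (without Scrambled 3) over left-out libraries and passed at -0.27 without Control 3 and Scrambled 2 (adjusted p = 0.0261, alternatives to 0.994).

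With the replicate number as a block, 3422, 2946, 2517 and 0 genes changed against Scrambled, Control, both controls and for Scrambled against Control, 26 of the 31 list calls were kept, those of matrix-degrading enzymes (adjusted p = 0.0554), histones (0.0615) and small RNA machinery (0.0554) against Scrambled and of fibroblast-like matrix (0.0719) and small RNA machinery (0.0589) against Control were not, 2 lists passed for Scrambled against Control, and CSF1R was -0.01. The numbers did not pair the libraries: same-numbered libraries deviated with r from -0.388 to 0.33, different numbers with r up to 0.624, and 0 libraries matched their own number best in both other groups.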

Other observations

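The splits of the libraries were fixed before their results were seen, and all tests of the 3' UTR heptamers, of microRNA sites and of the shared deviation of Control 3 and Scrambled 2 were chosen after, as were the 9 splits that keep the CA2 shRNA libraries together.

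Against Control, 21 lists that did not pass as a whole held members past the threshold, of which 7 are given here. Of 20 YAP and TEAD targets 4 rose and 8 fell (4 and 8 adjusted over the list alone, list adjusted p = 0.171, median -0.008), among them AXL, which fell from 888 ± 19.2 to 467 ± 31.9 CPM (SD, n = 3 each), and ANKRD1 (log2 change -0.67). Of 29 genes of G2 and mitosis 3 rose and 6 fell (3 and 8 adjusted over the list alone, list adjusted p = 0.208, median -0.068), with CCNB2 at -0.51 and CDC25C at -0.59. In the lysosome and autophagy list 4 of 26 members rose and 1 fell (5 and 1 adjusted over the list alone, list adjusted p = 0.231, median 0.041), with TFEB, a regulator of lysosomal genes, at 0.62 and MAP1LC3B at -0.55. Of 17 vacuolar ATPase subunits 3 rose and 2 fell (3 and 2 adjusted over the list alone, list adjusted p = 0.202, median 0.071), with ATP6V0E1 falling from 81.5 to 43.8 CPM. Of 22 acid-base and lactate transporters 4 rose and 1 fell (4 and 1 adjusted over the list alone, list adjusted p = 0.401, median 0.066), with SLC16A1 at 0.57 and SLC9A7 at -0.48. In the tricarboxylic acid cycle 3 of 22 rose and 4 fell (6 and 4 adjusted over the list alone, list adjusted p = 0.303, median 0.041), with SUCLG2 at 0.29. Of 14 hypertrophy and ossification genes 1 rose and 2 fell (1 and 2 adjusted over the list alone, list adjusted p = 0.322, median -0.178), with ENPP1 at -0.93. AXL, CCNB2, CDC25C, MAP1LC3B, ATP6V0E1, SLC9A7 and ENPP1 held at least 1 of the 3' UTR heptamers.

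Splits of the libraries bear on the counts of changed genes. Of 10 splits of the 6 libraries the real one gave 3348 genes against Scrambled and 2906 against Control, and the highest other gave 0 in each, with 1 of 10 reaching the real count in each. For Scrambled against Control edgeR's real count was 0 (550 at an unadjusted p under 0.05, 1 with DESeq2 and 0 with limma-voom), which 10 of 10 splits reached, and the highest other gave 1589. In these 3 comparisons 10 splits are too few for a share under 0.05. The split of Control 1, Scrambled 1 and Scrambled 3 against Control 2, Control 3 and Scrambled 2 was the one that called 1589 genes, which points to a structure of the samples. For both controls together 1 of 100 splits drawn from 840 reached the real 2470 genes, and the highest other drawn gave 485. The 9 other splits that keep the CA2 shRNA libraries together were not among those drawn and gave 2395 to 3120 genes, so the count does not rest on how the 6 control libraries are grouped. Several of these 9 exceeded the real count, and 3 of 9 libraries can be set apart in only 84 ways. Chance is thus made unlikely for setting these 3 CA2 shRNA libraries apart, but it is not excluded. A difference between single cultures stays open, since the labels do not say that the replicates are separate cultures.

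Of the scanned genes with ACACCAA or CACCAAA in the 3' UTR 678 fell against Scrambled, 130 rose and 1488 did not pass. Among 16251 heptamers these had the lowest z, -28.6 and -28.5 against Scrambled and -29.0 and -28.9 against Control, while the largest size over 100 shuffles was 5.1. Shuffling ignores correlation between genes: in Scrambled against Control, where edgeR called 0 genes, the lowest z was -5.6 (AGTATAT), beyond the shuffles in size. Of the 173 genes at least 2-fold lower against Scrambled 67 were in the scan, and 52 of these held a heptamer (77.6%, exact 95% interval 65.8 to 86.9) against 47.5% of all 1428 scanned falls, 8.4% of rises and 16.4% of scanned genes that did not pass, and the 523 genes with ACACCAAA had a median of -0.25 and, relative to genes with no site, shifted by -0.212 ± 0.062 (SD) in the 3 CA2 shRNA libraries against 0.108 ± 0.051 in the 6 others. The shifts were taken from each gene's mean over all 9 libraries, so the positive value in the 6 others follows from the negative one in the 3. The heptamers were picked from these same fold changes, so the shares, the interval and the shifts describe them and are no separate test. The shares were not matched for 3' UTR length, and both comparisons use the same 3 CA2 shRNA libraries. Base composition does not account for the whole of the falls. The lowest z of the 31 heptamers of the same bases that share no 6 adjoining bases with ACACCAAA was -8.4 (-8.5 against Control). AACACCA, which shares them, reached -13.4 (-12.9). All 31 lay below 0 (median -2.5 and highest -0.4, against Control -2.3 and -0.3), and -8.4 exceeds the shuffles in size. A contribution of base composition is therefore not excluded. The tables argue against depth, since the median of genes with ACACCAAA lay -0.311 from that of genes with no site after thinning and -0.308 before. A candidate explanation is silencing through a seed of the hairpin: CA2 itself holds ACACCAAA in its coding sequence (chromosome 8, 85474343 to 85474350, plus strand, exon 4 of 7, GRCh38), which 3.6% of 10489 transcripts do over the same length, and as the hairpin sequence is not given in the sources used here this stays a hypothesis.

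Of 11242 genes with neither heptamer in the searched 3' UTR 799 fell and 1432 rose against Scrambled in the test of all genes, and 2432 changed when tested alone. The set is not free of possible sites, since coding sequences and shorter 3' UTRs were not searched. Of scanned genes with 6 but not 7 adjoining bases of ACACCAAA 9.0% fell, against 6.5% with no site (8.9% and 5.8% against Control). Loss of CA2 may contribute to these 2432 changes, but there is 1 hairpin group and no rescue among the labels, so it and other effects of the hairpin cannot be told apart. TGF-beta targets (adjusted p = 0.000162, alternatives 1.01e-05 to 0.121), nuclear factor kappa B genes (0.000389, 2.00e-05 to 0.456), interferon-stimulated genes (0.0111, 3.17e-05 to 0.214) and endoplasmic reticulum stress genes (0.000389, 3.17e-05 to 0.488) kept their list calls there. Competition of the hairpin with endogenous microRNAs could raise genes with their sites: of 20 families, 4 had been noticed in these fold changes before, and the other 16 had a median z of 0.87 against Scrambled (percentiles 98.53 and 99.16 among 10000 random sets) and 0.58 against Control (91.61 and 88.9). The percentile of 88.9 leaves this open, and the difference between the comparisons was not tested.

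Control 3 and Scrambled 2 deviated together from their group means (r = 0.624 across genes, which are not independent replicates), with less NEAT1 (159 and 233 CPM) than the other control libraries. Their chi-square per gene of 3.7 was the lowest of any pair of libraries. The structure was not confined to them. Control 1 and Scrambled 3 had a chi-square per gene of 3.96, which was also below every pair within a group (lowest 4.64). Control 1 deviated opposite to Scrambled 2 (r = -0.506). Scrambled 2 also deviated with CA2 shRNA 3 (r = 0.403), and Scrambled 1 opposite to Control 3 (r = -0.437) and CA2 shRNA 3 (r = -0.488). A trend on GC content does not account for the whole of the deviation that Control 3 and Scrambled 2 share, since r was 0.588 after a correction. That correction lowered the largest rho of a library with GC content from 0.61 (Scrambled 1) to 0.05. Before it rho was -0.31 in Control 3 and -0.45 in Scrambled 2. Depth does not account for the whole either, with r = 0.564 after thinning. Other technical sources, such as a difference between batches of libraries, may remain after these values of 0.588 and 0.564, and no biological explanation was tested, since the labels give no group that holds these libraries.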
